A study of Mus musculus with 8 samples.

How the data were processed

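Expression was measured on 8 one-colour Affymetrix mouse arrays of V6.5 mouse embryonic stem cells. Per the labels, the cells were infected with lentivirus carrying a short hairpin RNA in medium with 8 µg/ml polybrene and kept in 4 µg/ml puromycin for 4 days. RNA was extracted on day 5 with Trizol and cleaned on columns, and 100 ng of total RNA gave biotin-labelled RNA by the 3' in vitro transcription protocol of the array maker. The 4 groups held 2 arrays each. The CapH2 knockdown (gene Ncaph2) was made with hairpins 3 and 4 and the Smc2 knockdown with hairpins 1 and 2, 1 array per hairpin. The Smc1 knockdown (gene Smc1a) and the control, a hairpin against GFP, were 2 biological replicates of 1 hairpin each.

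The deposited values are intensity, 1 linear summary per probe set and array, for 44903 probe sets. The way the authors summarised the probes is not given in the sources used here. The values themselves were checked: they ran from 0.0461 to 54756, were not on a log scale and were not quantile normalized, and the means over probe sets trimmed by 2% lay between 488.9 and 490.0 on all arrays, so each array had been scaled to a common mean. No detection calls or raw scans were used here. Array medians lay between 62.5 and 74.5, and their log2 values differed by less than the limit of 0.5 set for further normalization, so none was added. The number of arrays, 2 per group, limits the precision of every value. P-values of the main fit rest on 1 spread per gene, pooled over all 4 groups. In every comparison it mixes differences between hairpins (CapH2 and Smc2) with those between replicates of 1 hairpin (Smc1 and GFP). Since Smc1 and GFP have 1 hairpin each, effects of such a hairpin on other genes cannot be separated from those of its target.

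Values were analysed as log2(value + 16) in R 4.3.3. Of the 44903 probe sets, 34771 had exactly 1 gene symbol, 926 had several and 9206 had none; only the first were used, and the 64 array controls found among all of them were left out. Of those with 1 symbol, 34567 were matched to the gene table of the mouse assembly GRCm38.p6 by gene identifier, and 0 symbols changed. For each of 18140 genes the probe set with the highest mean stood for the gene. A gene was tested where it lay above the array's median on at least 2 of the 8 arrays, which left 12394 genes. No positions are given, because the sources used here name no genome build for the arrays.

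All 8 arrays were fitted together with limma 3.58.1 (group means, empirical Bayes moderation with an intensity trend, 4 residual and 5.97 prior degrees of freedom). The comparisons were each knockdown against GFP (3 tests), CapH2 against Smc2, and Smc1 against the mean of CapH2 and Smc2, called "the condensin knockdowns" below. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison, with no limit on the change. Errors of log2 changes are limma standard errors (SE). Gene lists were tested with camera from limma (preset correlation between genes of 0.01, Benjamini-Hochberg over the 26 lists of a comparison), again with an estimated correlation, and with fry, which asks whether a list moves one way on balance. Called members were counted over all genes tested and adjusted over the list alone. Fold changes that share the GFP arrays were correlated across genes and set against 1000 simulations without any effect in which the same arrays were shared, with the 97.5th percentile as the limit; shared calls were set against 100 simulated fits and signs against 200 simulations.

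The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the targeted gene, the 8 called genes with the largest rise and the 8 with the largest fall against GFP among those whose groups do not overlap, up to 4 called members of each list with the smallest adjusted p, all members of the 3 SMC lists, and Pou5f1, Nanog, Sox2, Klf4, Esrrb and Cdkn1a. In the 2 direct comparisons it named the 5 largest called differences each way and up to 2 called members per list. The 26 lists were condensin subunits, cohesin and its regulators, the Smc5/6 complex, naive and general pluripotency, epiblast and primed state, trophectoderm, primitive and extraembryonic endoderm, neural and ectoderm, mesendoderm and mesoderm, genes of the two-cell-like state, p53 targets, the integrated stress and unfolded protein responses, interferon response, G2/M and mitosis, DNA replication and S phase, DNA repair and damage signalling, histone genes, ribosomal proteins, Myc targets and ribosome biogenesis, polycomb and DNA methylation machinery, Mediator and RNA polymerase II pausing, imprinted genes, cholesterol synthesis, glycolysis and hypoxia, feeder fibroblast, and apoptosis. Of 882 listed entries, 631 genes were tested.

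The fit was tested on simulated data in which 50 genes were changed at each of 4 sizes. In the CapH2, Smc2 and Smc1 comparisons it called 50, 48 and 36% of genes changed by 1 on the log2 scale, and 88, 90 and 94% of those changed by 2. It made 3 false calls among 122, 5 among 129 and 11 among 126. Alternatives were quantile normalization, median centring over the tested genes, no filter, a filter at the 70th percentile, the mean of a gene's probe sets, pseudocounts of 1 and 64, no trend, array weights, fits of only the groups compared, a replicate block for Smc1 and GFP, a different GFP array for each fold change, and leaving out each array. Alternatives added later were a term for the ratio of the 3' to the 5' Actb control probe sets (a measure of how complete the labelled RNA is), a term for the first principal component of the residuals, a block that pairs the CapH2 and Smc2 arrays by number, the same over all groups, the mean of the 2 condensin knockdowns against GFP, the mean of the 3 knockdowns against GFP, and list tests after median centring or without the targeted gene. The residual component and the pairing of the CapH2 and Smc2 arrays leave the fold changes as they were and take up residual spread. The component comes from the residuals of the same fit, so part of any rise in calls with it is built in. Figures were drawn with matplotlib 3.10.9.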

Results

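The series asks how transcription depends on condensin II, which compacts chromosome arms, and on its relation to cohesin in mouse embryonic stem cells. Expression was measured on 8 arrays, 2 each for the CapH2 (condensin II), Smc2 (condensin I and II) and Smc1 (cohesin) knockdowns and the GFP hairpin control. Array medians lay between 62.5 and 74.5 intensity units. Across the genes tested, Pearson's r was 0.968 to 0.981 for the 4 pairs of arrays within groups and 0.914 to 0.985 for the 24 pairs between groups; genes are not independent replicates. The first principal component took 47.2% of the variance. On it the Smc1 arrays lay at -53.6 and -32.2 and the GFP arrays at 39.9 and 31.4, with CapH2 at -10.6 and 18.1 and Smc2 at -5.80 and 12.9 between them. The Actb 3' to 5' ratio, a sign of RNA and labelling quality, was 1.70 and 1.84 on the Smc1 arrays, 1.67 and 1.98 on CapH2 (hairpins 3 and 4), 1.82 and 2.18 on Smc2 (hairpins 1 and 2) and 2.18 and 2.04 on GFP. In the same order, the ratio of the Gapdh control probe sets was 0.833 and 0.862, 0.790 and 0.863, 0.813 and 0.845, and 0.864 and 0.857.

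Each targeted gene was lowest in its own knockdown. Ncaph2 measured 397.5 and 429.5 on the CapH2 arrays (hairpins 3 and 4), 3469 and 3168 on the GFP arrays, 2134 and 3049 on the Smc2 arrays and 2294 and 3075 on the Smc1 arrays. Its log2 change in the CapH2 knockdown was -2.96 (SE 0.218, n = 2 per group, limma adjusted p = 0.00115), which left 12.5% of the GFP mean. The 3 other Ncaph2 probe sets were at 36.04, 41.5 and 87.1%. Smc2 measured 2234 and 2859 on the Smc2 arrays (hairpins 1 and 2), 8756 and 7146 on GFP, 6088 and 7094 on CapH2 and 6466 and 6005 on Smc1. It fell by 1.64 on the log2 scale in its own knockdown (SE 0.172, adjusted p = 0.0154), to 32.03% of GFP, and 4 other probe sets were at 27.1, 29.3, 30.8 and 81.4%. Smc1a measured 534.8 and 453.8 on the Smc1 arrays, 4165 and 3662 on GFP, 3662 and 3840 on CapH2 and 3427 and 3572 on Smc2. It fell by 2.95 (SE 0.164, adjusted p = 7.81e-05), to 12.6% of GFP, with 2 other probe sets at 18.9 and 21.9%. The call of Ncaph2 was lost without GFP replicate 1 (-2.89, adjusted p = 0.0918) or GFP replicate 2 (-3.02, adjusted p = 0.0612). The call of Smc2 was lost without Smc2 hairpin 1 (-1.46, adjusted p = 0.0823), Smc1 replicate 1 (-1.64, 0.0674), Smc1 replicate 2 (-1.64, 0.0662), GFP replicate 1 (-1.49, 0.155) or GFP replicate 2 (-1.79, 0.118).

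**Figure D1:**
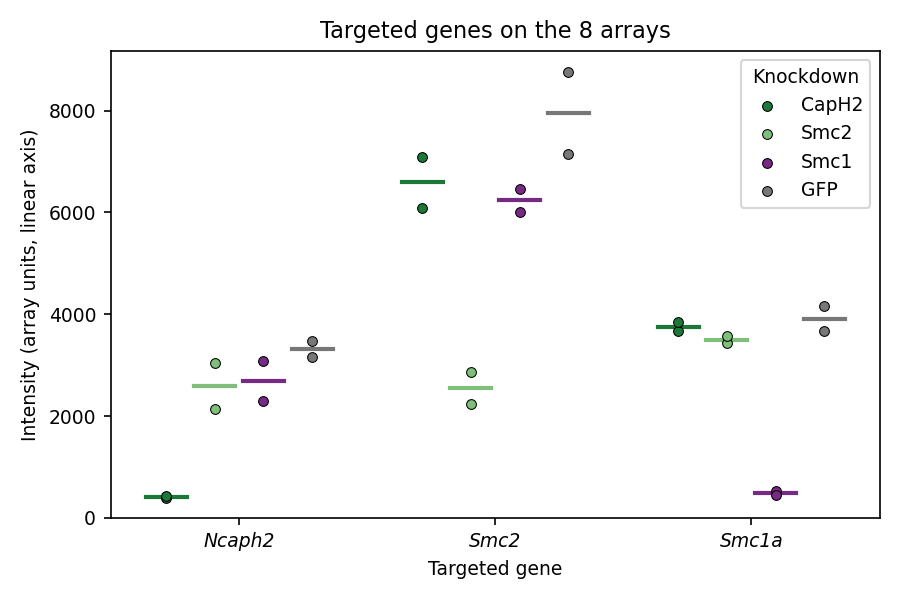
Intensity (linear axis) of the 3 targeted genes on each of the 8 arrays; points are arrays, bars are means of 2 arrays, and colours are knockdowns. Each gene is lowest on the arrays of its own knockdown: Ncaph2 at 397.5 and 429.5, Smc2 at 2234 and 2859, and Smc1a at 534.8 and 453.8.

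The CapH2 knockdown against GFP asks which genes depend on condensin II. Besides Ncaph2, 1 gene of 12394 was called: Hnrnpll, an RNA-binding splicing factor, rose from 1519 ± 96.6 to 5220 ± 507 (SD, n = 2 per group), a log2 change of 1.77 (SE 0.156, limma adjusted p = 0.00318). Its other probe set rose by 1.11. Pou5f1, Nanog and Sox2, the core pluripotency factors, were not called (-0.39, -0.26 and -0.21, adjusted p = 0.473, 0.394 and 0.641), nor was Klf4 (0.26, adjusted p = 0.574). The meiotic cohesin genes Smc1b (-1.62, adjusted p = 0.475) and Stag3 (-1.19, adjusted p = 0.366) were lower but not called. They were about as low in the Smc1 knockdown (-1.57 and -1.18). At an unadjusted p below 0.05 there were 1565 genes, where 619.7 would be reached by chance. The 2 CapH2 arrays lay above both GFP arrays in 3132 genes and below both in 2719, where chance gives 33.3% of the 12394. The count was 0 in limma without GFP replicate 1 (837 genes at an unadjusted p below 0.05, Hnrnpll at 1.70, adjusted p = 0.104) or GFP replicate 2 (1153 genes, 1.83, adjusted p = 0.0612). Without Smc2 hairpin 1 or Smc2 hairpin 2 it was 4. With terms chosen after the data were seen it was 2 (Actb ratio), 531 (first component of the residuals) and 297 (CapH2 and Smc2 arrays paired by number).

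Among gene lists in the CapH2 knockdown, camera placed the ribosomal proteins lower (41 genes, median -0.24, adjusted p = 1.34e-11, and adjusted p = 0.855 with an estimated correlation). The same second value, 0.855, held for the other 6 camera calls. Those were lower condensin subunits (median -0.27, adjusted p = 0.000526, or 0.0220 with the targeted Ncaph2 left out, a test added after the results were seen), G2/M genes (-0.25, 0.000178) and glycolysis genes (-0.26, 0.0117), and higher epiblast (0.59, 0.00299), neural (0.65, 0.0117) and two-cell-like genes (1.00, 0.00444). No member of these lists other than Ncaph2 was called. Adjusted over the list alone, 5 of 13 epiblast and 2 of 14 neural genes were. With quantile normalization the medians of the ribosomal proteins and the glycolysis genes were -0.01 and -0.13 and neither list was called (adjusted p = 0.338 and 0.123). Leaving out hairpin 3 left 1 of the 7 calls, leaving out GFP replicate 1 left 4, and leaving out GFP replicate 2 left 6. The medians of the stress response (-0.02, mean 0.02), replication (0.01, mean -0.01) and polycomb lists (-0.01, mean 0.09) differed in sign from their means, and none of these was called.

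The Smc2 knockdown against GFP asks the same for both condensins. Hnrnpll again was the only called gene besides the target: it rose to 5198 ± 645, a log2 change of 1.76 (SE 0.156, adjusted p = 0.00664), and by 1.16 on its other probe set. Pou5f1, Nanog, Sox2 and Klf4 were not called (-0.09, -0.16, -0.26 and 0.27, adjusted p = 0.877, 0.583, 0.570 and 0.565), and Smc1b (-1.69) and Stag3 (-1.26) were lower but not called (adjusted p = 0.449 and 0.341). There were 1560 genes at an unadjusted p below 0.05, against 619.7 by chance, and 2869 lay above and 2694 below both GFP arrays, against 33.3% by chance. The count depended on single arrays: 194 without Smc2 hairpin 2, 3 without CapH2 hairpin 3 or hairpin 4, 1 without either Smc1 replicate, and 0 in limma without Smc2 hairpin 1, GFP replicate 1 or GFP replicate 2 (731, 1026 and 938 genes at an unadjusted p below 0.05). With the terms chosen after the data were seen it was 53 (Actb ratio), 592 (first component of the residuals) and 345 (CapH2 and Smc2 arrays paired). Without Smc2 hairpin 1 or either GFP array Hnrnpll was not called, with 1.63 (adjusted p = 0.0524), 1.70 (0.0780) and 1.82 (0.118).

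In the Smc2 knockdown, camera placed the two-cell-like genes higher (10 genes, median 1.17, adjusted p = 0.00036, and adjusted p = 0.938 with an estimated correlation). The value 0.938 also held for the other 6 camera calls: higher epiblast (0.38, adjusted p = 0.00272) and neural genes (0.51, 0.0157, but 0.05 and 0.131 without the expression filter), and lower condensin subunits (-0.24, 0.00423, but 0.0682 and no call with the targeted Smc2 left out), trophectoderm genes (-0.44, 0.0103), ribosomal proteins (-0.10, 0.00906) and glycolysis genes (-0.21, 0.00272). Of their members only Smc2 was called. Adjusted over the list alone, 6 of 13 epiblast, 6 of 10 two-cell-like and 2 of 14 neural genes were. The ribosomal protein median was 0.00 after quantile normalization and 0.05 without GFP replicate 1, without a call. Leaving out Smc2 hairpin 1 left 1 of the 7 calls, GFP replicate 1 left 3 and GFP replicate 2 left 6. Medians and means differed in sign for the Smc5/6 (0.05 and -0.04), endoderm (-0.03 and 0.01), replication (0.01 and 0.00, the mean just below 0), histone (0.00 and -0.17) and polycomb lists (-0.03 and 0.06), which were not called.

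The direct comparison of the condensin knockdowns asks where condensin II and both condensins differ. Only Ncaph2 was called, lower in CapH2 by -2.58 (SE 0.218, adjusted p = 0.00416), and 128 genes had an unadjusted p below 0.05, fewer than the 619.7 given by chance. The other targeted gene, Smc2, was higher in CapH2 by 1.37 (1.31, 1.54, 1.63 and 0.21 on its other probe sets) but was not called. The comparison thus missed a targeted gene, and its 1 call does not show that the condensin knockdowns are alike. Arrays with the same number lay closer across these groups (r = 0.985 and 0.984) than the 2 arrays within CapH2 (0.974) or Smc2 (0.968), so that the error of this comparison holds a deviation shared by both groups. With a term for that pairing, chosen after the data were seen, 2 genes were called and 235 had an unadjusted p below 0.05. Hnrnpll (0.01) was not called, and 1555 genes were higher and 1272 lower on both CapH2 arrays, against 33.3% by chance. Without CapH2 hairpin 3 the count was 0 in limma (225 genes at an unadjusted p below 0.05, Ncaph2 at -2.53, adjusted p = 0.0532), and without Smc2 hairpin 2 it was 3. Camera placed primitive endoderm genes higher (median 0.34, adjusted p = 0.000382) and G2/M genes (-0.13, 0.000103) and ribosomal proteins (-0.14, 9.55e-13) lower in CapH2, each with adjusted p = 0.978 with an estimated correlation. The endoderm call was lost without CapH2 hairpin 3 (median 0.06, adjusted p = 0.544) or Smc2 hairpin 1 (0.06, 0.502). The G2/M median was 0.01 without CapH2 hairpin 3 and 0.04 without Smc2 hairpin 2, and with quantile normalization neither the G2/M genes (-0.08, adjusted p = 0.0517) nor the ribosomal proteins (-0.01, 0.639) were called. Medians, means or tests differed in sign for the pluripotency, epiblast, neural, histone, Myc and imprinted lists, none of them called.

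The Smc1 knockdown against GFP asks which genes depend on cohesin, and it had the most called genes of the comparisons. Among the largest rises, the immunoproteasome gene Psmb8 reached 1184 ± 342 (SD, n = 2 per group), against 27.8 ± 32.7 in GFP, a log2 change of 4.98 (SE 0.537, limma adjusted p = 0.00235). The interferon-induced GTPase genes Gbp7 (4.12), Gbp3 (4.07) and Irgm1 (3.99) rose too, as did Ms4a4d (4.90), the sulfotransferase gene Chst15 (4.46), Rtp4 (4.21) and the BMP target Id3 (4.13). The GFP means of these 8 genes, from 1.57 (Rtp4) to 70.4 (Gbp3), lay below or among the array medians of 62.5 to 74.5. Without detection calls it is not known whether they were above background in GFP. The sizes and the order of their changes are thus not firm. Among the largest falls were the cell cycle regulator Rgcc (-3.97), the stress gene Nupr1 (-3.53), Tspo2 (-3.47), Lrrc31 (-3.39), Lrrc34 (-3.07), the activin subunit gene Inhbb (-3.04) and the germline and naive pluripotency factor Prdm14 (-2.92). The Smc1 means of Tspo2 (25.6), Lrrc31 (40.03) and Inhbb (57.6) lay below the array medians, so the sizes of these falls are not firm either. A dimmer probe set of Inhbb did not fall (0.21), while that of Nupr1 did (-3.29). Hnrnpll, singled out after the values were seen, was higher by 1.78, and by 1.09 on its other probe set.

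In all, 1734 genes were called in the Smc1 knockdown, 1153 higher and 581 lower, and 813 and 319 of these by at least 2-fold. Of the risen genes 171 had a GFP mean, and of the fallen 52 a Smc1 mean, below the lowest array median, so that the sizes of their changes are not firm. Of those named below these include Oasl2, Cnn1, Cdx2, Arg2, Bcl2, Col3a1, Ifit2 and Sox1. There were 3870 genes at an unadjusted p below 0.05, and 4282 lay above and 3516 below both GFP arrays, against 33.3% by chance. The share of called genes that were higher, 66.5%, depended on the kind of scaling. With quantile normalization it was 63.0% (1117 of 1772). Median centring moved the median log2 change of all genes from 0.03 to -0.10 and gave 907 higher and 1035 lower genes, 46.7% higher, of which 1488 were among the 1734. The count was 138 without Smc1 replicate 1, 1046 without Smc1 replicate 2, 228 without GFP replicate 1 and 555 without GFP replicate 2. Of the 91 calls of genes named by rule, these leave-outs kept 24, 68, 35 and 47. With terms chosen after the data were seen the count was 569 (Actb ratio, 472 of them among the 1734), 3340 (first component of the residuals) and 2944 (CapH2 and Smc2 arrays paired).

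Of the pluripotency genes called in the Smc1 knockdown most were lower. Pou5f1 fell from 12484 ± 1636 to 7267 ± 2468 (-0.82, SE 0.215, adjusted p = 0.0340), Sox2 by 0.88 (adjusted p = 0.0143) and Nanog by 0.73 (adjusted p = 0.00525). The naive-state factors Klf4 (-1.49), Esrrb (-1.57), Tcl1 (-2.67), Prdm14 (-2.92) and Pecam1 (-2.12) fell further. Of 38 pluripotency genes 19 were lower, 3 higher and 16 not called (21 and 3 adjusted over the list alone, median -0.61, camera adjusted p = 5.02e-07, and adjusted p = 0.532 with an estimated correlation; fry adjusted p = 0.0805). Of 13 epiblast genes 5 were called higher (6 adjusted over the list alone), among them Pou3f1 (2.23), Cldn6 (1.85), Sox3 (1.59) and Sox4 (1.29), with a median of 1.17 (camera adjusted p = 0.00121, and adjusted p = 0.532 with an estimated correlation). Pluripotency counts were 5 lower and 0 higher without Smc1 replicate 1, without GFP replicate 1 8 and 0, and without GFP replicate 2 7 and 1. The epiblast count was 0 without Smc1 replicate 1, 2 without Smc1 replicate 2, 1 without GFP replicate 1 and 2 without GFP replicate 2.

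**Figure D2:**
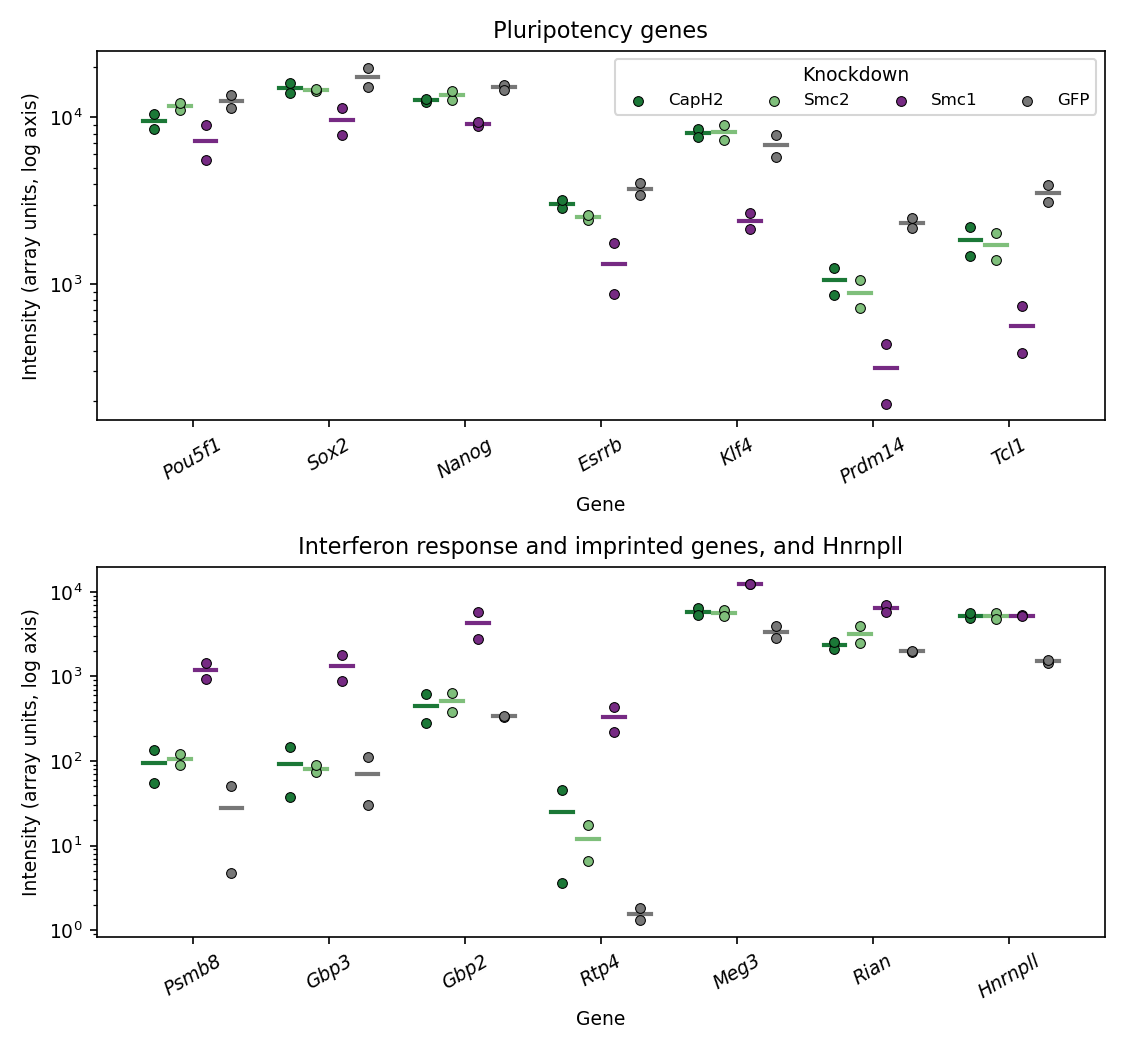
Intensity (log axis) of 7 pluripotency genes and of 7 genes higher in the Smc1 knockdown, on each of the 8 arrays; points are arrays, bars are means of 2 arrays. Klf4 is lower than in GFP on the Smc1 arrays only, while Hnrnpll lies near 5220 in all 3 knockdowns and at 1519 in GFP.

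Lineage genes moved both ways in the Smc1 knockdown. In mesendoderm and mesoderm 5 of 15 genes were higher (9 higher and 1 lower adjusted over the list alone, median 1.02, camera adjusted p = 0.00121, and adjusted p = 0.532 with an estimated correlation), all of the 4 named coding for contractile proteins: Cnn1 (3.82), Myl9 (3.18), Actc1 (3.06) and Tagln (2.43). In trophectoderm 6 of 21 were higher and 1 lower (8 and 1 adjusted over the list alone, median 0.41), with Krt19 (2.73) and Cdx2 (2.52) up and Tfap2c (-1.51) down. Of 21 primitive endoderm genes 3 were higher and 2 lower (7 and 2 adjusted over the list alone, median 0.52), with Serpinh1 (1.28) and Dab2 (1.79) up and Apoe (-1.06) and Lamc1 (-0.98) down. Of 14 neural genes 4 were higher and 4 lower (5 and 4 over the list alone, median 0.28): Sox11 rose (1.72), while Sox1 (-2.29), Olig2 (-2.20) and Stmn2 (-0.98) fell. Camera called none of these 3 lists (adjusted p = 0.0722, 0.0641 and 0.889). Of 10 two-cell-like genes 3 were higher (7 adjusted over the list alone, median 1.41, camera adjusted p = 0.00517, and adjusted p = 0.532 with an estimated correlation): Usp17la (3.09), Arg2 (2.42) and Zfp809 (1.14). Without Smc1 replicate 1, Smc1 replicate 2, GFP replicate 1 and GFP replicate 2, in that order, called genes numbered 3, 5, 3 and 4 in mesendoderm, 2, 4, 2 and 3 in trophectoderm, 0, 3, 0 and 3 in endoderm, 3, 4, 2 and 3 among neural genes, and 0, 5, 2 and 0 in the two-cell-like list, which had 5 without either Smc2 array. The two-cell-like list was not called by camera without Smc1 replicate 1 (median 0.94, adjusted p = 0.0579).

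Feeder fibroblast markers, a control for other cells in the culture, were higher in part. Of 37 listed, 27 were measured above the filter and 5 were called higher (10 higher and 1 lower adjusted over the list alone, median 0.61, camera adjusted p = 0.00692, and adjusted p = 0.532 with an estimated correlation). Ccn2 (2.02), Col3a1 (1.92), Ccn1 (1.79) and Lgals1 (1.32) were higher, while the abundant Vim (-0.07, 6685 against 7257) and Fn1 (-0.01) and the collagen gene Col1a2 (-0.04) were not called. The count was 0 without Smc1 replicate 1, 1 without GFP replicate 1, 2 without GFP replicate 2, and 8 without CapH2 hairpin 3 or hairpin 4. Camera did not call the list without GFP replicate 1 (median 0.47, adjusted p = 0.0558).

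The interferon response genes called in the Smc1 knockdown, which act in antiviral defence, all rose. Of 30 genes 16 were higher and 0 lower in limma (17 and 2 adjusted over the list alone; 1.67 in the median; camera adjusted p = 1.61e-06, and adjusted p = 0.441 with an estimated correlation; fry adjusted p = 0.0271). Besides Psmb8, Oasl2 rose by 3.73, Gbp2 by 3.51, from 338.7 ± 4.50 to 4288 ± 2128, and Ifi35 by 2.45. In the CapH2 and Smc2 knockdowns the medians of this list were 0.21 and 0.10, without a called gene, though adjusted over the list alone 1 was higher and 1 lower in each. There Ifit2, chosen after its values were seen, was higher by 2.15 and 2.37 (2.54 in Smc1) and Psmb8 by 1.46 and 1.70, none of these 4 called. The GFP means of Ifit2 (14.4) and Psmb8 lay below the array medians, so the sizes of these changes are not firm. The count was 6 without Smc1 replicate 1 and 10 without GFP replicate 1.

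Most called imprinted genes were higher too: 9 of 31 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.00607, and adjusted p = 0.352 with an estimated correlation; fry adjusted p = 0.00819). The maternally expressed noncoding RNAs Meg3 and Rian, neighbours at 1 imprinted locus, rose by 1.89 (3384 ± 805 to 12410 ± 134) and 1.67, as did Ndn (1.43) and Gnas (0.87). The count of risen genes was 3 without Smc1 replicate 1, 4 without GFP replicate 1 and 6 without GFP replicate 2.

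The called replication and repair genes were all lower in the Smc1 knockdown, but most genes of both lists were not called. In replication and S phase 8 of 39 were lower (11 adjusted over the list alone, median -0.36, camera adjusted p = 1.32e-08, and adjusted p = 0.441 with an estimated correlation; fry adjusted p = 0.0271), with Rrm2 (-0.64), Gins1 (-0.75), Prim1 (-0.72) and Ung (-0.96). In repair 6 of 33 were lower (12 adjusted over the list alone, median -0.38, camera adjusted p = 1.24e-06, and adjusted p = 0.532 with an estimated correlation; fry adjusted p = 0.0722), with Chek1 (-0.96), Brca1 (-0.97), Fancd2 (-1.07) and Rad54b (-1.34). Among stress response genes 5 of 32 were lower and 1 higher (6 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 0.0016, and adjusted p = 0.352 with an estimated correlation; fry adjusted p = 0.0271). Nupr1, Psat1 (-0.97) and Asns (-0.69) fell and Atf3 rose (1.26). Dlgap5 (-0.80) was the 1 called gene of 39 in G2/M (0 adjusted over the list alone, median -0.22, camera adjusted p = 0.00103, and adjusted p = 0.583 with an estimated correlation). Of 40 p53 targets 7 were higher and 1 lower (8 and 1 over the list alone, median 0.16, camera adjusted p = 0.149), with Ddit4l (1.91), Plk2 (1.56) and Ccng1 (0.60) up and Rrm2b (-1.54) down. Cdkn1a missed the threshold (0.74, adjusted p = 0.0510). Leaving out Smc1 replicate 1, Smc1 replicate 2, GFP replicate 1 and GFP replicate 2, in that order, called genes numbered 0, 4, 0 and 3 in replication, 0, 8, 0 and 1 in repair, 1, 3, 1 and 1 in the stress response, 0 each in G2/M, and 0, 1, 0 and 0 among p53 targets. Without either Smc2 array G2/M had 3 or 4, and without GFP replicate 1 camera did not call it (median -0.09, adjusted p = 0.0697). After median centring 15 replication and 13 repair genes were lower.

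Among genes of the SMC complexes, Smc1a was the strongest fall of the cohesin list. Esco2 (-1.41), Sgo1 (-0.67) and Wapl (-0.59) also fell (another bright probe set of Wapl rose by 0.43), and Rec8 (1.35) and Stag1 (0.82) rose, so that 4 of 20 were lower and 2 higher (4 and 2 adjusted over the list alone, median -0.27, camera adjusted p = 0.0130, and adjusted p = 0.532 with an estimated correlation; without the targeted Smc1a camera did not call the list, adjusted p = 0.0641). Smc3 (-0.40), Rad21 (-0.16), Nipbl (0.17) and Ctcf (-0.31) were not called (adjusted p = 0.113, 0.400, 0.650 and 0.245). Smc1b (-1.57) and Stag3 (-1.18) were not called either, and lay near their values in CapH2 (-1.62 and -1.19) and Smc2 (-1.69 and -1.26). No condensin subunit of 8 was called by limma, with Ncapd3 at -0.55, Smc4 at -0.54 and Ncaph at -0.54 (adjusted p = 0.0913, 0.0765 and 0.0727); the list's median was -0.47 (camera adjusted p = 0.00208, and adjusted p = 0.532 with an estimated correlation). After median centring 3 condensin subunits were called lower. Nsmce4a (-0.56) was the 1 called gene of 6 in the Smc5/6 complex (2 adjusted over the list alone, median -0.11, camera adjusted p = 0.188). The cohesin list had 1, 3, 2 and 1 called genes, and the Smc5/6 list 0 each, without Smc1 replicate 1, Smc1 replicate 2, GFP replicate 1 and GFP replicate 2. Without GFP replicate 1 the Smc5/6 median was 0.01. Without either Smc2 array the Smc5/6 list had 2 and the condensin list 1.

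The remaining lists had few called genes in the Smc1 knockdown. Of 41 ribosomal proteins Rps25 (-1.11) and Rpl12 (-1.02) fell (1 adjusted over the list alone, median -0.14, and 0.00 without GFP replicate 1; camera adjusted p = 0.000115, and adjusted p = 0.583 with an estimated correlation). In glycolysis and hypoxia Vegfa fell (-1.69) and Slc2a1 (0.47) and Pdk1 (0.57, but -0.30 and -0.52 on 2 dimmer probe sets) rose, of 25 (median -0.25, camera adjusted p = 0.0448, and adjusted p = 0.656 with an estimated correlation). Camera did not call glycolysis without Smc1 replicate 1 (adjusted p = 0.285), GFP replicate 1 (0.0697) or GFP replicate 2 (0.0631), nor the ribosomal proteins without GFP replicate 1 (0.345), and with quantile normalization it called neither (0.198 and 0.331). Of 22 polycomb and DNA methylation genes 2 were higher and 3 lower (2 and 4 over the list alone, median -0.17, camera adjusted p = 0.159), including Bmi1 (1.05), Suz12 (-0.76), Mtf2 (-0.79) and Tet2 (-1.07). Of 21 apoptosis genes Casp8 (1.50), Apaf1 (0.79) and Bcl2 (2.16) rose (4 adjusted over the list alone, median 0.13, camera adjusted p = 0.0900). The probe set of Bcl2 had a mean of 59.4, below the array medians, and its 4 other probe sets were at -0.77, -0.20, -0.18 and 0.09. No gene was called among 34 Myc targets (median -0.13, adjusted p = 0.0641), 38 Mediator and pausing genes (0.13, 0.612), 20 cholesterol genes (-0.09, 0.376) or 7 histone genes (-0.18, 0.132). Called genes without Smc1 replicate 1, Smc1 replicate 2, GFP replicate 1 and GFP replicate 2 numbered 0, 0, 0 and 2 among ribosomal proteins, 0, 2, 0 and 2 in glycolysis, 0, 4, 0 and 0 in polycomb and 0, 3, 0 and 1 in apoptosis. The cholesterol median was 0.19 without Smc1 replicate 2 and 0.02 without GFP replicate 1. Of the 15 lists called by camera in this comparison, 0 held with an estimated correlation, as in the other comparisons. Fry called 4 here and the same 4 in the direct comparison below, and 0 elsewhere: the interferon, replication, stress response and imprinted lists.

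**Figure D3:**
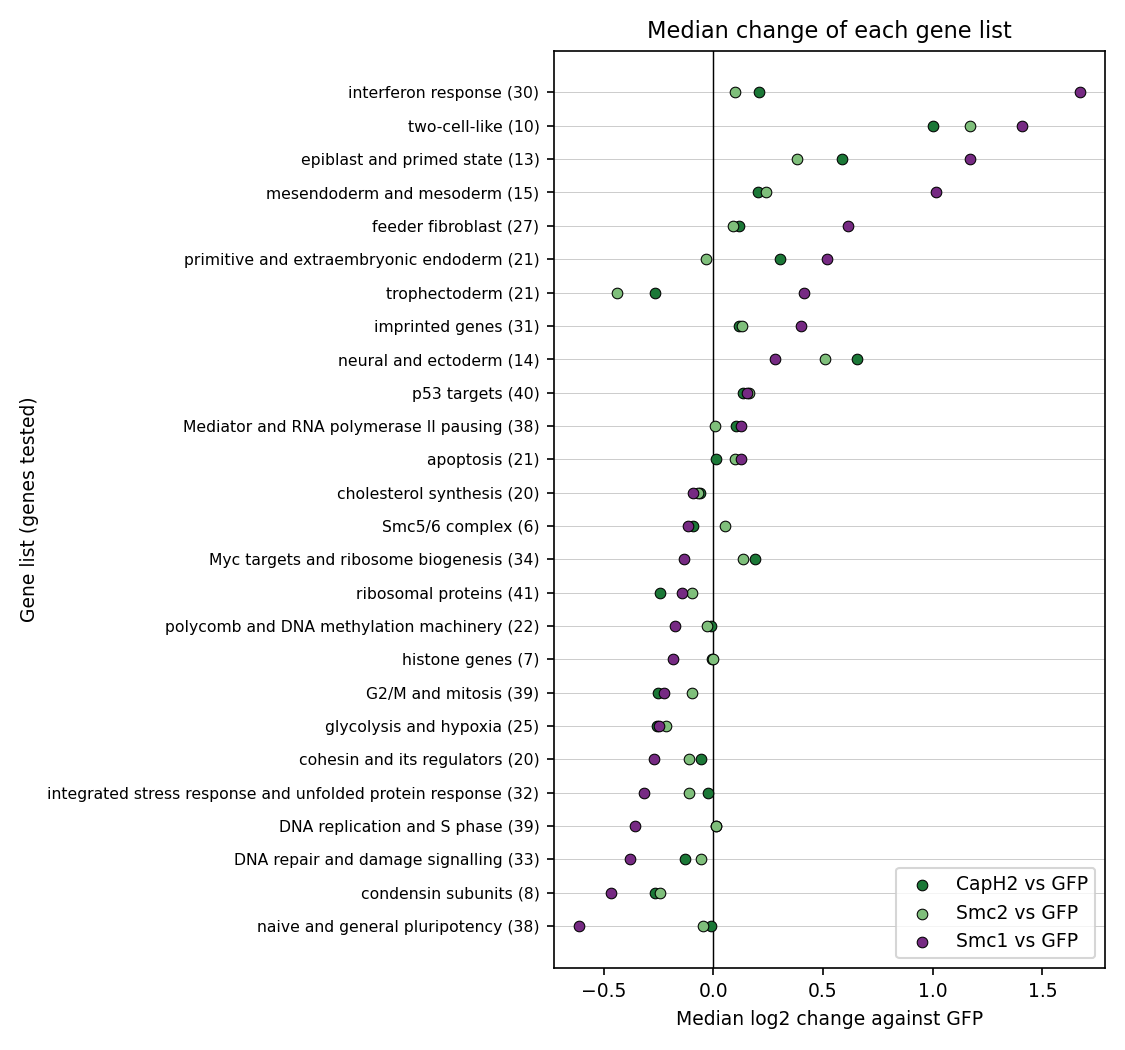
Median log2 change against GFP (x axis) of the tested genes of each of 26 lists (y axis, genes tested in parentheses) in the 3 knockdowns. Interferon genes lie at 1.67 in Smc1 but at 0.21 and 0.10 in CapH2 and Smc2, and pluripotency genes at -0.61 in Smc1 only; two-cell-like genes lie at 1.00 or above in all 3.

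The direct comparison of the Smc1 with the condensin knockdowns asks which changes are particular to cohesin. Klf4 was lower in Smc1 by -1.76 (SE 0.164, adjusted p = 0.0021), with 2397 ± 372 against 8086 ± 633 in CapH2 and 8156 ± 1162 in Smc2. Inhbb (-3.42), Nupr1 (-3.19), the sodium channel gene Scn3a (-3.02), Sox1 (-2.86) and Smc1a (-2.84) had the largest falls, and Gbp3 (3.75), Synpo2l (3.51), Psmb8 (3.40), Rtp4 (3.40) and Cxcl10 (3.35) the largest rises. A dimmer probe set of Inhbb was at -0.16. Cdkn1a, the cell cycle inhibitor p21, was higher in Smc1 by 1.41 (adjusted p = 0.00542), but this joined a rise in Smc1 (0.74) with falls in CapH2 (-0.72) and Smc2 (-0.62) against GFP, none of them called. The Smc1 means of Inhbb (57.6), Scn3a (1.68) and Sox1 (47.9) and both condensin means of Synpo2l (27.0 and 37.4) and Rtp4 (24.7 and 12.03) lay below the array medians. The sizes of these differences and the order of the largest falls and rises are thus not firm. In all 961 genes were called, 685 higher and 276 lower, 441 and 107 of them by at least 2-fold, and 2926 had an unadjusted p below 0.05. After median centring 498 were higher and 465 lower (51.7% higher instead of 71.3%), 774 of them among the 961. With quantile normalization 65.4% were higher. In 2537 genes both Smc1 arrays lay above and in 1807 below all 4 condensin arrays, against 13.3% by chance. The count was 9 without Smc1 replicate 1, 384 without Smc1 replicate 2, 467 without CapH2 hairpin 4, 582 without GFP replicate 1 and 567 without GFP replicate 2. With the later terms it was 1646 (Actb ratio), 2037 (first component of the residuals) and 1701 (CapH2 and Smc2 arrays paired). Of 41 calls of genes named by rule, 5 were kept without Smc1 replicate 1 and 29 without Smc1 replicate 2.

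Camera called 10 lists in this direct comparison. Interferon genes were higher (15 of 30 called, 18 adjusted over the list alone, median 1.22; adjusted p = 7.61e-11, and adjusted p = 0.210 with an estimated correlation), as were trophectoderm genes (10 of 21 higher and 1 lower, 12 and 1 adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.587 with an estimated correlation), among them Krt19 (2.82) and Rhox6 (1.67, from a called rise of 1.07 in Smc1 and changes of -0.51 and -0.68 in CapH2 and Smc2 against GFP that were not called). Mesendoderm (5 higher and 1 lower; adjusted p = 0.00243, and adjusted p = 0.587 with an estimated correlation), imprinted (8 and 1, 0.00829, and adjusted p = 0.210 with an estimated correlation) and feeder genes (4 and 1, 0.0336, and adjusted p = 0.613 with an estimated correlation) were higher. Pluripotency (16 of 38 lower and 1 higher, 21 and 3 adjusted over the list alone; adjusted p = 2.46e-10, and adjusted p = 0.365 with an estimated correlation) and replication genes (8 of 39 lower, 23 adjusted over the list alone; 2.55e-13, and adjusted p = 0.210 with an estimated correlation) were lower. So were repair genes (4 of 33, 7.51e-09, and adjusted p = 0.365 with an estimated correlation), stress response genes (5 of 32, 0.000779, and adjusted p = 0.210 with an estimated correlation) and, with no called gene, Myc targets (median -0.30; 3.35e-05, and adjusted p = 0.613 with an estimated correlation). Camera did not call the mesendoderm, imprinted and feeder lists without Smc1 replicate 1 (adjusted p = 0.0870, 0.0675 and 0.163), nor the feeder list without CapH2 hairpin 4 (0.134). Called genes without Smc1 replicate 1 numbered 0 of the interferon, trophectoderm, imprinted, replication, repair, stress and feeder genes and 1 of the mesendoderm and of the pluripotency genes. Without Smc1 replicate 2 there were 3 of the trophectoderm, replication and mesendoderm genes each, 2 of the stress and feeder genes and 1 of the repair genes. Without CapH2 hairpin 4 there were 9 of the pluripotency, 3 of the feeder, 2 of the repair and 1 of the replication genes, and without CapH2 hairpin 3 5 of the replication genes. Without GFP replicate 1 or GFP replicate 2 there were 3 of the replication and stress and 2 of the feeder genes, and without Smc2 hairpin 2 13 of the replication genes and 6 Myc targets. Medians and means differed in sign for condensin subunits (-0.23 and 0.06), where Ncaph2 (1.35) and Smc2 (0.61) were higher in Smc1 (1 other probe set of each at -0.22 and -0.70), and ribosomal proteins (0.01 and -0.04), and the tests of the Mediator (0.00) and cholesterol lists (0.09) pointed down; none was called.

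Across the 12394 genes the fold changes of the 3 knockdowns went the same way. For CapH2 and Smc2 Pearson's r was 0.851 (Spearman's rho 0.824, covariance 0.172), for CapH2 and Smc1 0.660 (0.639, 0.208), and for Smc2 and Smc1 0.653 (0.623, 0.210). The shared GFP arrays alone gave a simulated r of 0.5003 (upper limit 0.517) and covariance of 0.0446. With a different GFP array for each fold change r was 0.529, 0.458 and 0.457, and the covariances were 0.129, 0.165 and 0.168. Each control then kept 1 array, so that part of the excess can still come from what both GFP arrays share. Without GFP replicate 1 the r of CapH2 and Smc1 was 0.663 and that of Smc2 and Smc1 0.658, below the simulated limit of 0.678. The simulations hold no changed gene, and changes in 1 knockdown alone lower r. Values below this limit thus do not show that shared controls explain these correlations. Genes are not independent replicates. Of the 1734 genes called in Smc1, 90.5% had the same sign in CapH2 and 89.6% in Smc2, against 86.0% in simulations with shared controls. These simulations hold no changed gene and pick genes by their noise alone. The 86.0% is thus no measure for genes that did change in Smc1. Genes higher in Smc1, by 1.27 in the median, were higher by 0.48 in CapH2 and 0.45 in Smc2, and the lower ones (-1.06) were at -0.37 and -0.41. The shared controls alone move these medians the same way, and by how much was not simulated. Hnrnpll was the only gene called in all 3 comparisons. For a pair of comparisons, simulated fits shared 0.02 or 0.01 calls on average. Those fits hold no changed gene, so they are no measure for an overlap with 1734 calls. Independent calls would share 8.07e-05 (CapH2 with Smc2) or 0.0930 (either with Smc1).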

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

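The terms for the Actb ratio and for the first residual component, 2 blocks by array number, the mean of the knockdowns against GFP, and the list tests after median centring or without the targeted gene were tests chosen after the data were seen; the other alternatives were fixed earlier. Under every alternative in which they were refitted the 3 targeted genes stayed lower in their own knockdown. The call of Smc1a and the fold change correlation of CapH2 with Smc2 held under all alternatives run. The cause was not tested for any of the shifts below, except that leaving out arrays or fitting only some groups leaves fewer arrays and residual degrees of freedom, and that without the filter more genes are tested.

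For 1734 calls in Smc1 against GFP, quantile normalization, median centring, both pseudocounts, array weights, no trend, both filters and the mean of probe sets stayed within 1.5-fold (1218 to 2398). The replicate block gave 1366. Within-group differences of Smc1 and GFP had a correlation of 0.067, and the labels do not say whether a replicate number marks a shared batch. Fits of only the groups compared gave 10 calls for CapH2, 0 for Smc2 (limma, Smc2 itself at -1.64, adjusted p = 0.0649), 2701 for Smc1, 0 for CapH2 against Smc2 and 598 for Smc1 against the condensin knockdowns. The mean of probe sets gave 1, 1 and 0 calls for CapH2, Smc2 and CapH2 against Smc2, with Ncaph2 at -1.44 (adjusted p = 0.0688) and Smc2 at -1.40 (adjusted p = 0.194). No trend gave 1, 0 and 0, with Smc2 at -1.64 (adjusted p = 0.123). Hnrnpll lost its call without the trend in both CapH2 and Smc2, and in Smc2 with fits of only the groups compared. Quantile normalization gave 2 calls in CapH2 against Smc2, and no filter gave 594 in Smc1 against the condensin knockdowns.

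With the Actb ratio as a term the counts were 2 for CapH2, 53 for Smc2, 569 for Smc1, 2 for CapH2 against Smc2 and 1646 for Smc1 against the condensin knockdowns. With the residual component they were 531, 592, 3340, 2 and 2037, and with a block that pairs the CapH2 and Smc2 arrays by number, which for these groups stands for different hairpins, 297, 345, 2944, 2 and 1701. Neither term changes the fold changes. Both were chosen after the data were seen and take up residual spread, so part of the rise in calls is built in. A block over all 4 groups gave 3, 3, 2206, 1 and 1178. The mean of CapH2 and Smc2 against GFP had 3 called genes (Hnrnpll 1.76, Ncaph2 -1.67, Snrpa1 0.92), 9 with quantile normalization, 1117 with the residual component, 580 without Smc2 hairpin 2, 16 without CapH2 hairpin 4, 1 or 2 without another knockdown array, and 0 in limma without either GFP array (1097 and 1278 genes at an unadjusted p below 0.05).

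Leaving out 1 array, where the lone array of a group is assumed to vary like the others, gave 0 to 4 calls for CapH2, 0 to 194 for Smc2, 138 to 2190 for Smc1, 0 to 3 for CapH2 against Smc2 and 9 to 1163 for Smc1 against the condensin knockdowns. Ncaph2 ranged from -3.02 to -2.89 and Smc2 from -1.82 to -1.46. The lowest and highest fold change correlations were 0.470 and 0.719 for CapH2 with Smc1 and 0.562 and 0.714 for Smc2 with Smc1. Those without GFP replicate 1 (0.663 and 0.658) lay below the simulated limit of 0.678. That limit holds no changed gene, so it cannot show that shared controls explain these correlations.

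The ribosomal protein list reversed in Smc2 against GFP with quantile normalization (0.00356) and without GFP replicate 1 (0.0451, lowest -0.24 without GFP replicate 2), and in Smc1 against GFP without GFP replicate 1 (0.000705, lowest -0.28 without GFP replicate 2). The G2/M list in CapH2 against Smc2 reversed without CapH2 hairpin 3 (0.00943) and without Smc2 hairpin 2 (0.0407, lowest -0.32 without Smc2 hairpin 1). Of the other list results with all arrays, 118 kept their side and 49 lost the call, 42 of these with an estimated correlation; with 1 array left out 300 kept their side and 32 lost the call. Results of named genes kept their status, called or not called, in 2413 cases, gained a call in 19 and lost it in 103. With 1 array left out these were 1659, 6 and 279. Genes called in neither fit count as kept even where the sign of their change turned. Signal over background limits dim genes: with a pseudocount of 16, changes of genes near or below 16 intensity units are pulled toward 0.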

Other observations

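The patterns and most tests were chosen after the results were seen, and only the tests of matched Actb ratios, of the interferon list between hairpins, of the residual component and of neighbouring genes had their prediction written before their own result; the limits that allow for deviations shared between arrays were added later.

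The fold changes of all 3 knockdowns went the same way. Independent noise of the shared GFP arrays is not the whole cause, since the lowest correlation with a different GFP array for each fold change was 0.457, against a limit of 0.0211 simulated with independent arrays. The lowest covariance of 0.129 exceeded the 0.0433 estimated for deviations shared between single arrays from the within-group differences. That estimate is no maximum: shared deviations of arrays with unlike numbers can cancel in it, and those common to a group do not show. A shift of the GFP arrays alone stays open: the covariance of Smc1 minus Smc2 with CapH2 minus GFP, which share no array, was 0.0358, above a limit of 0.00142 for independent arrays but below the 0.0502 estimated in the same way for shared deviations. RNA or labelling differences read by the Actb ratio stay open: arrays matched in it (CapH2 hairpin 4 with GFP replicate 2, Smc2 hairpin 2 with GFP replicate 1) gave differences correlated at 0.285, above a limit of 0.0237, but that limit too took the arrays as independent, wrongly, and the covariance of 0.0571 lay below the 0.102 between the 2 hairpin differences of these groups. A response common to the loss of condensin and cohesin cannot be told apart from a shift of the controls, because there is 1 control hairpin.

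For Hnrnpll, singled out for its like changes, the 3 knockdowns differed by at most 0.0162 on the log2 scale (95% margin 0.348), while all lay 1.77 above GFP. An effect of the GFP hairpin and an equal response to the 3 knockdowns would both give this, and with 1 control hairpin they cannot be told apart. The mean of the 3 knockdowns against GFP called 418 genes, 315 higher and 103 lower. In 64 of them (51 higher and 13 lower), Hnrnpll among these, the spread of the 3 changes stayed within 0.25 times the mean change. Another 61 differed among the 3 knockdowns. By this limit Hnrnpll was not alone in its like changes, but the limit is wide: Bend3 passed with a spread of 0.47 on a mean change of 1.89. The genes were also picked on the same GFP arrays, which favours like changes, and no number expected without effects is given. The 418 became 8 without GFP replicate 1, 1 without GFP replicate 2, 54 without Smc1 replicate 1, 157 without CapH2 hairpin 3, and 802 and 1176 without CapH2 hairpin 4 and Smc2 hairpin 2.

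CapH2 hairpin 3 and Smc2 hairpin 1 deviated together from the other hairpin of their group, with a correlation of 0.410 between the differences (0.259 and 0.209 with that of the Smc1 replicates). Within-group differences in the Actb ratio took 44.6% of the residual variance, near the 45.1% of the first component and above the upper limit of 41.0% for random directions, so RNA or labelling quality may lie behind this deviation. The Gapdh ratio differed the same way between these hairpins but by less (log2 -0.126 and -0.0567, against -0.248 and -0.262 for Actb). Unequal knockdown cannot be told apart, as the targeted gene was lower by a mean of -0.23 on the deviating arrays, within a margin of 0.437. The calls gained with the residual component (531 in CapH2) stay open: 40 simulated sets with such a component and no group effect gave a median of 6 calls, but 5 of them gave at least 531. The same differences had a correlation of 0.451 (CapH2) and 0.252 (Smc2) with Smc1 minus GFP, with which they share no array.

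For the genes called in the Smc1 knockdown, the Actb ratio may be a source of part of the changes: with it as a term the median change of the 1734 genes went from 1.20 (median SE 0.259) to 0.95 (0.287), and 569 genes were called, 472 of them shared. It is not the whole cause if equal ratio differences act alike: as many genes, picked on 1 Smc1 and 1 GFP array, changed by medians of 0.98 and 1.35 on the other 2 (ratio differences of -0.15 and -0.36), but by at most 0.435 between hairpins (-0.25 and -0.26), or 0.443 if scaled up to the larger ratio difference. The Gapdh ratio, which was not used as a term, differed less between these groups, with 0.833 and 0.862 on Smc1 and 0.864 and 0.857 on GFP. The interferon list moved by 0.469 and -0.29 between hairpins, against 1.67 in Smc1. A response to virus or selection alike in all groups, GFP included, would cancel against GFP, so the rise of the interferon list cannot test it. The 15 genes called higher in Smc1 than in the condensin knockdowns show only that the rise was larger in Smc1, on the same Smc1 arrays. Without Smc1 replicate 1 the median of this difference was still 1.22. A response to virus or selection that was unequal between groups was not tested and stays open. An effect of the 1 Smc1 hairpin on other targets cannot be told apart from the loss of Smc1a.

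Whether genes that are neighbours on the chromosome (order from the assembly GRCm38.p6) were called together in the Smc1 knockdown was a hypothesis of this re-examination. Among 10893 adjacent pairs that do not overlap and do not share the first letters of their symbol, 186 were called in the same direction, against a median of 118 and an upper limit of 139 in 1000 shuffled orders. Shuffles within chromosomes reached 155 at most, so a shift of whole chromosomes is not the whole cause. Rank correlations of neighbours were 0.0864 for Smc1, 0.0784 for Smc2 and 0.0555 for CapH2, which share the GFP arrays, 0.0287 for CapH2 minus Smc2 and 0.00734 for the difference of the 2 GFP arrays. Changes that spread over adjacent genes may contribute, but likeness of neighbours in regulation was not tested.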
